A study of Homo sapiens with 28 samples.

How the data were processed

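The series holds 28 samples in 14 groups of 2, per the labels all from HEK293, a human embryonic kidney line, with poly(A) RNA. The 12 samples in 6 groups with a processed table are used here. They are RNA-seq of cells given DMSO, dasatinib, hydroxychloroquine or levofloxacin for 60 minutes, and cells given a levofloxacin probe with a photoreactive diazirine group for 30 minutes, with and without a competitor according to the titles alone. The other 16 samples, 8 groups of the probe-based profiling method that maps reactions of acylating drug analogues with RNA, were not analysed here.

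The 4 deposited tables list transcripts by Ensembl identifier. The submitters' processing notes name Bowtie2 and GRCh38 without giving their role, and the annotation, the rule for reads that map to several places and the filter on listed transcripts are not given in the sources used here. Per the file headers the library columns have no unit. The deposited library values are therefore called a score, whose form was read from the values. They are whole numbers. In short transcripts, under 200 nt or under 1500 nt in the diazirine table, nearly all low values fall on whole multiples of a constant divided by transcript length. This was not resolved in the DMSO libraries or in diazirine replicate 2, where the same form was assumed. The score was thus taken to be RPKM, a read count divided by transcript length and library depth, rounded to whole numbers by the authors, and not a count itself. Per the file headers the authors also deposited a log2 fold change, which recomputation showed to be the log2 ratio of the group means of the score without a pseudocount. The deposited p-value column was recomputed as an unadjusted 2-sample test of equal variance on the score, one-sided for dasatinib and hydroxychloroquine and two-sided for the diazirine probe, and the levofloxacin table has no such column. The deposited −log10 column of the diazirine table is the −log10 of its p-value. None of these derived columns entered the tests below.

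The DMSO values had 0 cells that differ between the 3 RNA-seq tables, so the tables share 1 scale. The 10184 transcripts listed in all 3 tables, out of 12951 in any, were used. GENCODE 29 held 9791 of them, and the other 393 were left out. A gene's value was the mean of its listed transcripts, a choice made after the tables were seen, and 1577 of the 3630 genes had 2 or more listed transcripts. The diazirine table lists 7547 transcripts of 2963 genes, of which 2947 were tested. The design had provided for counts, for normalized values such as RPKM, or for the authors' comparisons alone, and the case of normalized values was followed.

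Read depth was read from the step between low values, in transcripts under 200 nt in the RNA-seq tables and under 1500 nt in the diazirine table. By this measure dasatinib replicates 1 and 2 held 3.39e+06 and 3.355e+06 reads, those of hydroxychloroquine 8.457e+06 and 6.494e+06 reads, and those of levofloxacin 3.985e+06 and 4.254e+06 reads. Diazirine replicate 1 held 2.824e+06 reads and the competitor libraries 1.658e+06 and 6.342e+05 reads. In these columns 94.0% to 99.7% of the values used lay within rounding (0.5) of a whole number of reads, against 41.1% to 70.1% by chance given the size of the steps. Steps were not resolved in either DMSO library or in diazirine replicate 2, so their depth is unknown. In a transcript of 1000 nt 1 read was worth a score of 0.118 to 0.298 in the drug libraries and 1.58 in competitor replicate 2. In a transcript of 70 nt it was worth 1.69 to 4.26 in the drug libraries.

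Values were compared with limma (trend) on log2(score + 1) for genes with a mean of at least 1, with group as the only term. One fit held the 8 RNA-seq libraries (4 residual degrees of freedom, prior 2.71) and another the 4 diazirine libraries (2 residual degrees of freedom, prior 4.14). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and the threshold was 0.05. The p-values measure only the spread between the 2 samples of each group, which the labels call biological replicates. The fit pools this spread over all its groups, so a p-value for 1 drug also rests on the spread of the other groups. Errors are SD with n = 2 unless a 95% interval of the log2 fold change is given. Gene lists with at least 5 tested members were compared with the other genes by camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists of a comparison. The same test was run with the correlation estimated from the data, and fry was run beside it. Member counts were also taken adjusted over the list alone. Responses of a pair of drugs were compared by Pearson's correlation across genes, set against 100 simulations of unchanged groups that share the DMSO libraries, which also gave the genes shared by chance.

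The 23 lists covered immediate-early genes, ERK pathway output, YAP-TEAD targets, dasatinib protein targets, lysosome, autophagy, cholesterol synthesis, unfolded protein and integrated stress response, p53 targets, topoisomerases, hypoxia, heat shock and metal response. They also covered mitochondrially encoded proteins, snoRNP proteins, box H/ACA and box C/D snoRNAs, snoRNA host genes, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts, blood cells and squamous epithelium. The mitochondrial, histone and snoRNA lists were included as checks of RNA quality, so a change in them need not be a response to a drug. Named genes followed a rule. In each comparison it took the 8 highest and 8 lowest fold changes past the threshold whose replicates did not overlap between groups and whose mean lay above the median gene. Where no gene passed it took the 4 smallest p-values in each direction, given as not passing. From each list with at least 5 tested members it took up to 4 members past the threshold by smallest p, or, where none passed, the 2 with the highest mean. The protein targets ABL1, SRC, TOP2A and TOP2B were added. Groups, tests, lists, this rule and the first set of alternative settings below were fixed before the data were examined. Coordinates are from GENCODE 29 on GRCh38.

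The fit was tested on simulated data with these group sizes and 1 spread per gene, pooled over the groups. Groups of unequal spread, such as DMSO and dasatinib here, were thus not simulated. For dasatinib against DMSO it recovered 35.8%, 80.6% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 5.56% false calls. For hydroxychloroquine against levofloxacin it recovered 40.3%, 71.6% and 95.5%, with 5.48% false calls. For the diazirine comparison it recovered 0% at each of these folds.

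That set held pseudocounts of 0.1 and 5, no filter, a mean of at least 5, the 4 samples of a drug and DMSO alone, replicate number as a block, leaving out each library, a fold of at least 1.5, an estimated correlation, and genes above the median mean. Added after the data were seen were median centring of each library, the transcript with the highest mean per gene, protein-coding genes only, genes without a listed transcript that holds a run of at least 30 adenines, each drug's whole table with its 4 samples, the drug contrasts without the DMSO libraries, and each drug of a pair against a different DMSO library. R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were used.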

Results

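RNA levels were measured in HEK293 cells after 60 minutes with DMSO, the vehicle, or with 1 of 3 drugs. Dasatinib inhibits ABL and SRC family kinases, hydroxychloroquine is an antimalarial that accumulates in lysosomes, and levofloxacin is a fluoroquinolone antibiotic that targets bacterial topoisomerases. Each of these 4 groups had 2 libraries. A further table held a levofloxacin probe with a diazirine, a group that ultraviolet light crosslinks to its neighbours, after 30 minutes, with 2 libraries of the probe alone and 2 whose titles carry the word comp, read here as a competitor. The series asks where drugs meet RNA in cells, and the RNA-seq groups give the levels of the transcripts themselves. Values are the deposited score, taken to be RPKM rounded to whole numbers, averaged over the listed transcripts of a gene. Depth ranged from 3.355e+06 to 8.457e+06 reads in the drug libraries and was not resolved in the DMSO libraries. In mid-length transcripts, below 2000 nt, the SD of the log2 ratio between replicates was 0.189 for DMSO, 0.400 for dasatinib, 0.293 for hydroxychloroquine and 0.316 for levofloxacin.

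The DMSO libraries stood apart from the drug libraries. On the first principal component, 48.0% of the variance over 3630 genes, they lay at −27.3 and −24.4 and the 6 drug libraries between 2.40 and 15.1. The second component, 21.1%, held dasatinib at 14.9 and 17.4 and the other 6 libraries between −9.39 and 2.11. Across genes, which are not independent replicates, log2 values of DMSO and drug libraries correlated at 0.888 to 0.925, and hydroxychloroquine and levofloxacin libraries correlated with each other at 0.963 to 0.972, like replicates of 1 group (0.954 to 0.985). The labels give no batch, so this split and the difference between DMSO and drug cannot be separated within these tables. Mitochondrially encoded transcripts took 21.6% and 20.1% of the summed score in DMSO, 21.8% and 24.6% with dasatinib, 18.0% and 15.5% with hydroxychloroquine, and 15.2% and 16.1% with levofloxacin.

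**Figure D1:**
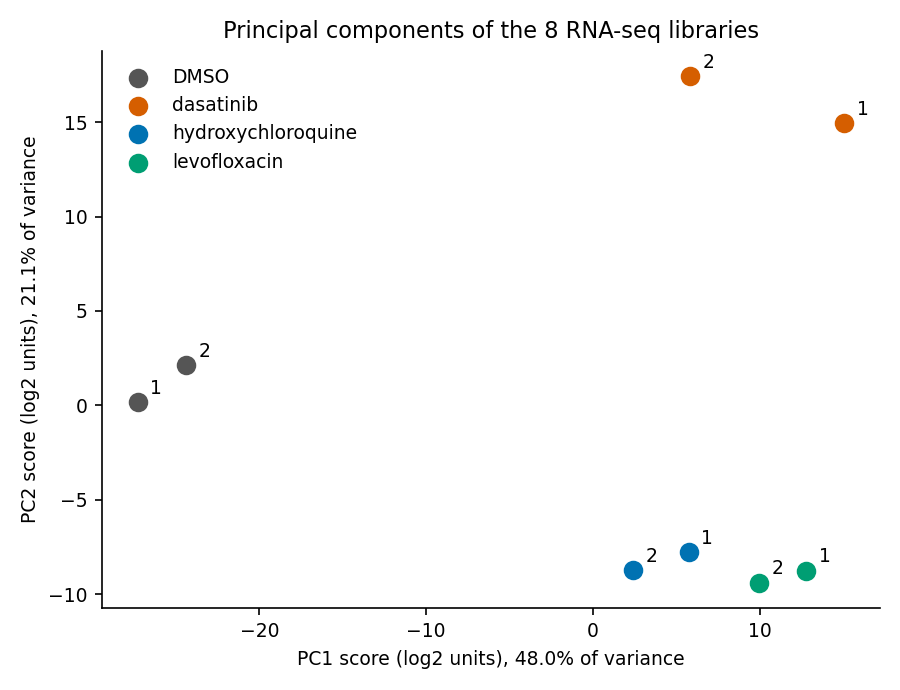
Scores of the 8 RNA-seq libraries on principal components 1 and 2 of log2(score + 1), one point per library, coloured by group. The DMSO libraries lie at −27.3 and −24.4 on component 1 and all 6 drug libraries at 2.40 or above.

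Dasatinib against DMSO asked which transcripts differed after 60 minutes of a kinase inhibitor. Among heat shock genes, whose products fold and refold proteins, 6 of 7 tested rose (camera adjusted p = 0.112 with an estimated correlation). HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) rose from 12.5 ± 2.12 to 109.5 ± 3.54 (SD, n = 2 per group), a log2 fold change of 3.04 with a 95% interval of 2.72 to 3.36. Its neighbour HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) rose from 28.5 ± 0.707 to 232.5 ± 17.7. Of 10 genes that cells induce when amino acids run short or unfolded proteins accumulate 7 fell and 1 rose (5 and 1 with centring, camera adjusted p = 0.647 with an estimated correlation). SESN2 (ENSG00000130766, chromosome 1, 28259527 to 28282491), a stress-induced inhibitor of mTORC1 signalling, fell from 75.5 ± 2.12 to 17 ± 0, and PSAT1 (ENSG00000135069, chromosome 9, 78297143 to 78330093), an enzyme of serine synthesis, fell from 191.8 ± 5.30 to 53.2 ± 2.47.

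The heat shock list had 7 tested members. With dasatinib 6 rose and 1 did not pass, and 7 rose adjusted over the list alone, with a median log2 fold change of 1.19. HSPA8, the constitutive chaperone, rose by 1.38 and HSPE1, a mitochondrial co-chaperonin, by 1.19, while HSPD1 lay at 0.26 (limma adjusted p = 0.081). Camera gave this list an adjusted p = 4.07e-10, and adjusted p = 0.112 with an estimated correlation. With median centring all 7 passed. Leaving out DMSO replicate 1 kept 4 of the members past the threshold and leaving out DMSO replicate 2 kept 5. The DMSO libraries stood apart from all drug libraries in these genes too, since every heat shock member named here was higher with each of the other drugs as well.

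The unfolded protein and integrated stress response list had 10 tested members, of which 7 fell, 1 rose and 2 did not pass with dasatinib (7 and 1 adjusted over the list alone). ASNS, asparagine synthetase, fell from 26.8 ± 0 to 6.04 ± 1.12, XBP1, a transcription factor of the unfolded protein response, fell by 1.02 on the log2 scale, and SDF2L1, a chaperone of the endoplasmic reticulum, rose by 0.95. The p53 target list fell in 6 of 9 members (8 adjusted over the list alone), with 3 not past the threshold. CDKN1A, the cell cycle inhibitor p21, fell from 15.6 ± 0.849 to 4.50 ± 1.27, TNFRSF10B, a death receptor, from 17.5 ± 1.41 to 7.75 ± 0.354, and RRM2B, a ribonucleotide reductase subunit, by 1.09 on the log2 scale. Camera gave adjusted p = 0.0494 and 0.00611 for these lists, and adjusted p = 0.647 and 0.422 with an estimated correlation. With centring 5 members of each list fell. The members that fell numbered 4 and 2 without DMSO replicate 1, 4 and 3 without DMSO replicate 2, and 6 and 4 without dasatinib replicate 1, and SDF2L1 did not pass without either DMSO library or dasatinib replicate 2.

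Immediate-early genes, which growth factor signals through kinases induce within minutes, fell in 4 of 8 members with dasatinib and 4 did not pass (4 fell adjusted over the list alone). EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) fell from 25.5 ± 6.36 to 2.50 ± 0.707, a log2 fold change of −2.91 (−3.57 to −2.26), and FOS fell from 13 ± 2.83 to 5.50 ± 0.707. JUND and SRF fell by 0.45 and 0.56 on the log2 scale. The list as a whole did not pass (camera adjusted p = 0.490), and with centring EGR1 alone passed. EGR1 passed without each of the 4 libraries in turn, while the list's count was 1 without either DMSO library and 2 without either dasatinib library.

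Of 82 cytosolic ribosomal protein genes 41 fell, 1 rose and 40 did not pass (46 and 1 adjusted over the list alone), with a median of −0.37. RPL3, a large subunit protein, fell from 125.3 ± 10.1 to 75.0 ± 1.77 and RPLP0, of the ribosomal stalk, by 0.67 on the log2 scale. Mitochondrially encoded protein genes, subunits of the respiratory chain, rose in 1 of 13 members. This was MT-ND6 (ENSG00000198695, mitochondrial genome, 14149 to 14673), from 354.5 ± 24.7 to 849 ± 17.0, and the 12 others did not pass. Camera gave adjusted p = 2.61e-04 and 2.54e-04, and adjusted p = 0.751 and 0.665 with an estimated correlation. With centring 11 ribosomal protein genes fell, and 0 adjusted over the list alone, while 2 mitochondrial ones rose. The ribosomal count rested on single libraries, being 0 without DMSO replicate 1, 9 without DMSO replicate 2 and 18 without dasatinib replicate 2, and the mitochondrial count was 3 without dasatinib replicate 1.

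The remaining lists gave few calls with dasatinib. The box H/ACA list, meant for guides of pseudouridylation and taken by the names SNORA and SCARNA, had 1 of 36 members higher. This was SCARNA7, by 1.13, which is known as a box C/D RNA of Cajal bodies, so no H/ACA snoRNA was called. The list had a median of −0.12 and a mean of −0.04, although camera placed the list up relative to other genes (adjusted p = 0.0412, and adjusted p = 0.751 with an estimated correlation), a call that centring ended (adjusted p = 0.248). Box C/D snoRNAs, guides of ribose methylation, had 2 of 88 higher and 6 lower (0 and 0 adjusted over the list alone, 2 and 2 with centring), SNORD69 falling by 2.16 on the log2 scale. Lysosome genes fell in 2 of 7 members (such as PSAP by 0.53), autophagy genes in 1 of 5 (GABARAP by 0.50) and snoRNP proteins in 2 of 8 (DKC1 by 0.55, FBL by 0.62). Cholesterol synthesis genes rose in 1 of 7 (SQLE by 0.54), snoRNA host genes rose in 1 (SNHG3) and fell in 3 of 11, and 1 of 22 replication-dependent histones was called higher, HIST1H2BG, whose run of 30 adenines puts it among the genes not read as expression. With centring 1 lysosome, 1 snoRNP and 0 autophagy genes fell. Camera adjusted p was 0.266 or more for these 7 lists. Without DMSO replicate 1 none of these calls passed except SCARNA7, and without DMSO replicate 2 only 2 box C/D snoRNAs and 2 host genes did. Dasatinib replicate 1 left out gave 4 members of the box H/ACA list and 2 histones lower, no cholesterol, autophagy or snoRNP call and 1 lysosome call. With dasatinib replicate 2 left out box C/D calls were 5 higher and 9 lower, 2 box H/ACA snoRNAs were higher, 2 histones were lower, and 0 autophagy genes and 1 snoRNP passed. TOP2A and TOP2B, the topoisomerases II, lay at −0.12 and −0.14 and did not pass, and ABL1 and SRC were not among the genes tested.

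In all, limma called 1031 of 3630 genes at the threshold, 224 higher and 807 lower. The median gene lay at −0.21, which centring moved by 0.13, and with centring 324 were higher and 456 lower, with 223 and 456 called alike under both scalings. The counts of named genes that follow include genes with a run of at least 30 adenines, which are not read as expression. Of 49 named genes past the threshold 18, among them HSPA1A, SESN2, PSAT1, EGR1, ASNS and MT-ND6, passed without each library in turn, and all 49 kept their sign. The count was 158 without DMSO replicate 1 and 299 without DMSO replicate 2.

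Apart from HSPA1A the 8 highest dasatinib fold changes were of genes with a listed transcript that holds a long run of adenines. AC007098.1 (ENSG00000231609, chromosome 2, 62957326 to 63048640), an antisense RNA with a run of 50, rose from 86.0 ± 11.3 to 892.5 ± 431, and to 624 ± 256 with hydroxychloroquine and 934 ± 342 with levofloxacin. ZNF302, a zinc finger gene with a run of 49, rose by 3.22, 2.73 and 3.31, and ADAM10, a membrane protease gene with a run of 48, by 3.11, 2.66 and 3.20. All 8 of the highest genes for hydroxychloroquine and for levofloxacin were of this kind. Among 55 tested genes with a run of at least 30 adenines 50, 48 and 50 rose and 0 fell with dasatinib, hydroxychloroquine and levofloxacin, by limma with the same threshold. The 67 listed transcripts with such a run had a median log2 fold change over the drugs of 2.40, against −0.07 in the 9276 transcripts whose longest run was under 12. These values are given as measured, and levels of such transcripts are not read as expression of their genes.

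**Figure D2:**
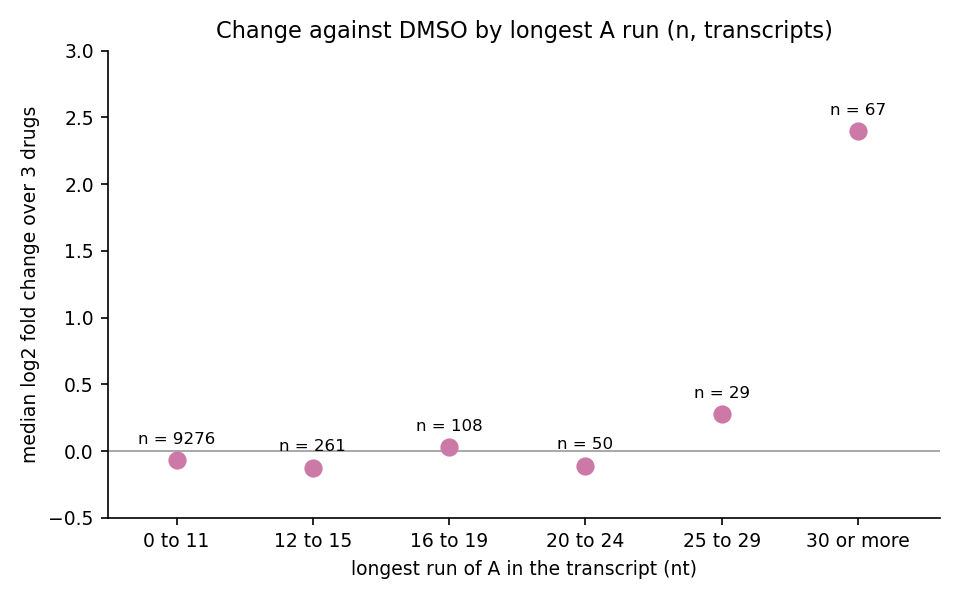
Median log2 fold change against DMSO over the 3 drugs, vertical axis, of transcripts grouped by their longest run of adenines in nt, horizontal axis, with the number of transcripts in each group. It is −0.07 below 12 adenines, 0.28 from 25 to 29 in 29 transcripts and 2.40 at 30 or more in 67 transcripts.

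**Figure D3:**
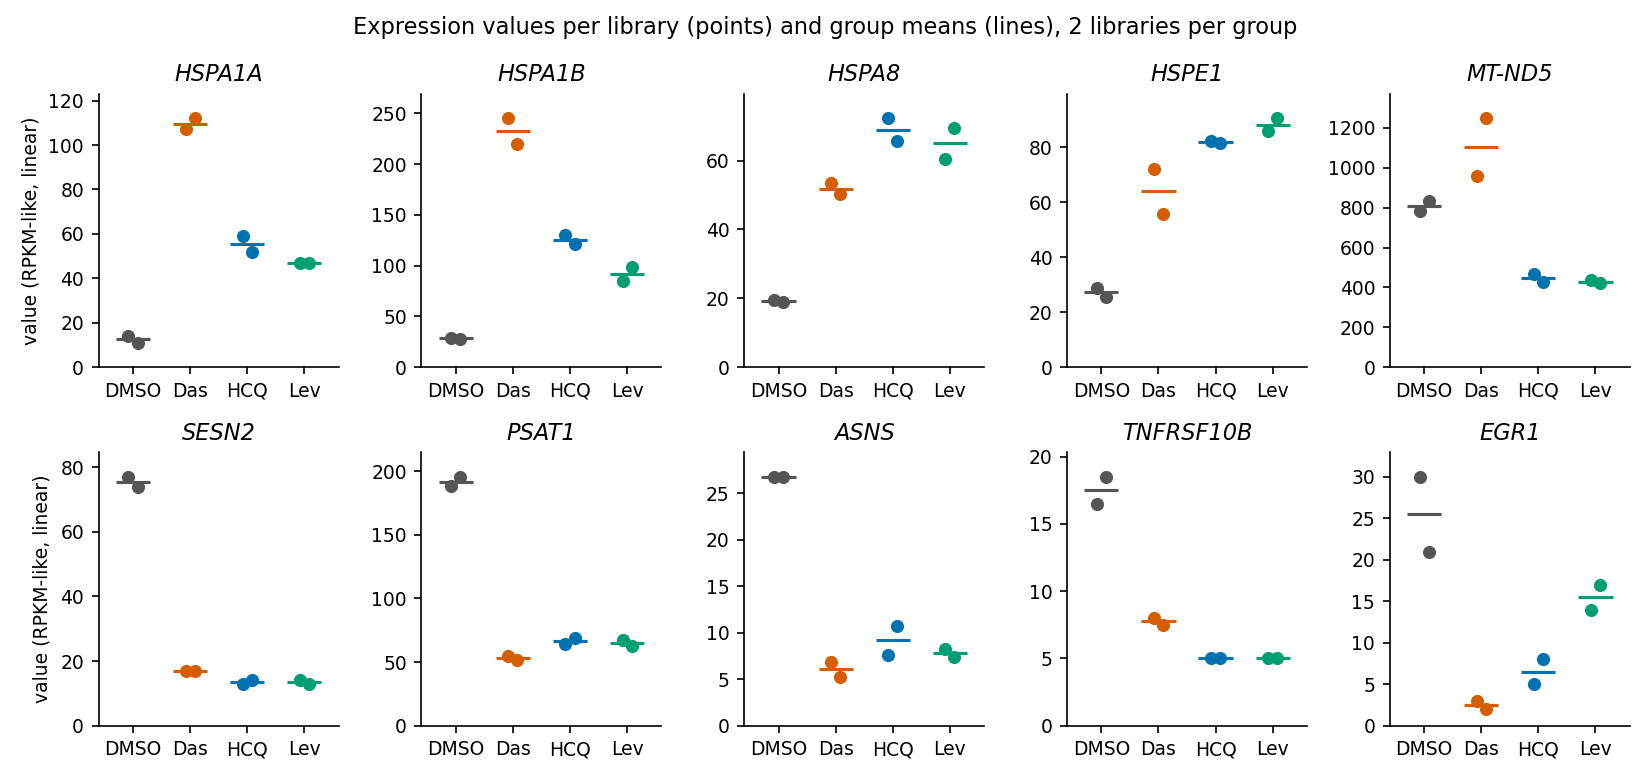
Score (linear axis) of 10 named genes in the 8 RNA-seq libraries, one panel per gene, with points for libraries and lines for group means, n = 2. HSPA1A lies at 12.5 in DMSO and at 47 or above in each drug, SESN2 at 75.5 in DMSO and at 17 or below, and MT-ND5 lies below DMSO with hydroxychloroquine and levofloxacin and above them with dasatinib.

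Hydroxychloroquine against DMSO asked the same question for a drug that accumulates in lysosomes. All 7 heat shock genes rose (7 adjusted over the list alone). HSPA1B rose to 125.5 ± 6.36, HSPA8 from 19.3 ± 0.447 to 68.9 ± 4.69 and HSPE1 from 27.2 ± 2.24 to 81.9 ± 0.354, with a list median of 1.56. Stress response genes fell in 6 of 10 members, with 4 not past (6 adjusted over the list alone), SESN2 to 13.5 ± 0.707, PSAT1 to 66.5 ± 2.83 and ASNS to 9.17 ± 2.24. The p53 targets fell in 5 of 9, with 4 not past (6 adjusted over the list alone), CDKN1A to 4.30 ± 0.707, TNFRSF10B to 5.00 ± 0 and BAX, a pro-apoptotic protein, by 1.26 on the log2 scale. Camera gave adjusted p = 1.70e-07, 0.0022 and 1.57e-04 for these lists, and adjusted p = 0.171, 0.255 and 0.171 with an estimated correlation. In each of these genes the DMSO libraries, which stood apart on the first component, lay on 1 side of all 6 drug libraries. Calls numbered 4, 2 and 1 in the 3 lists without DMSO replicate 1, 4, 2 and 0 without DMSO replicate 2, 7, 3 and 1 without hydroxychloroquine replicate 1, and 6, 4 and 5 without hydroxychloroquine replicate 2.

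Immediate-early genes fell in 4 of 8 members with hydroxychloroquine and 4 did not pass (4 fell adjusted over the list alone), with a median of −0.79. JUND, a subunit of AP-1, fell from 30.8 ± 2.47 to 11 ± 0.707, EGR1 to 6.50 ± 2.12, FOS to 4.50 ± 2.12 and SRF by 1.05 on the log2 scale. Mitochondrially encoded genes fell in 5 of 13 (9 adjusted over the list alone, and 8 of 13 with centring), with 8 not past. MT-ND5 (ENSG00000198786, mitochondrial genome, 12337 to 14148) fell from 809.5 ± 34.6 to 446 ± 26.9 and MT-ND1 from 1057 ± 62.2 to 544 ± 1.41. Camera gave both lists adjusted p = 5.90e-04, and adjusted p = 0.318 and 0.637 with an estimated correlation. Without any 1 of the DMSO or hydroxychloroquine libraries 0 mitochondrial genes passed in limma. The immediate-early count was 1 without either DMSO library and JUND passed without each library in turn.

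Among other lists, lysosome genes, the drug's site of accumulation, showed 1 member higher (ATP6V0E1, a proton pump subunit, by 0.69), 2 lower (such as LAMP1 by 0.56) and 4 of 7 not past, with camera adjusted p = 0.184. None of 5 autophagy genes passed in limma (camera adjusted p = 0.182), and GABARAPL2 and GABARAP lay at −0.27 and −0.22. Cholesterol synthesis genes rose in 2 of 7 (IDI1 by 0.60, ACAT2 by 0.79), snoRNP proteins in 2 of 8 (NHP2 by 0.54, NOP10 by 0.71), and ribosomal protein genes rose in 3 and fell in 1 of 82 (RPL22L1 by 0.96, RPS26 by 0.47 and RPS15 by 0.46, against RPL3 at −0.51). Box C/D snoRNAs rose in 1 and fell in 6 of 88 and box H/ACA snoRNAs fell in 1 of 36 (SCARNA4). Host genes fell in 1 of 11 (SNHG25) and histones rose in 1 of 22 (HIST1H4B by 0.78). Hypoxia response genes rose in 3 of 4, PGK1 and LDHA, glycolytic enzymes, by 0.68 and 0.71 and BNIP3, a mitophagy receptor, by 0.93, and with centring 1 passed. TOP2A and TOP2B lay at 0.09 and −0.09 and did not pass. Leaving out DMSO replicate 1 or DMSO replicate 2 left 0 calls in every list of this paragraph. Hydroxychloroquine replicate 1 left out kept 1 box C/D call and 2 hypoxia calls and gave box H/ACA snoRNAs 1 higher and 1 lower, with 0 in the others. Hydroxychloroquine replicate 2 left out kept 2 box C/D calls and the H/ACA, host and histone calls and gave 1 cholesterol gene higher and 1 lower, with 0 in the others.

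Limma called 769 of 3630 genes with hydroxychloroquine, 420 higher and 349 lower, and with centring 340 were higher and 461 lower, with 340 and 349 called alike under both. Of 52 named genes past the threshold 7 (SESN2, PSAT1, JUND, HSPA1A, HSPA1B, HSPA8 and HSPE1) passed without each library in turn, and all 52 kept their sign. The count was 31 without DMSO replicate 1, 29 without DMSO replicate 2, 193 without hydroxychloroquine replicate 1 and 286 without hydroxychloroquine replicate 2. MIR6087, a listed microRNA locus, fell from 1133.5 ± 24.7 to 256.5 ± 12, and RNA5SP162, a 5S ribosomal RNA pseudogene whose reads can belong to its many copies, from 264.5 ± 60.1 to 86.5 ± 29.

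Levofloxacin against DMSO asked the same question for an antibiotic. All 7 heat shock genes rose (7 adjusted over the list alone), with a median of 1.65. HSPA8 rose to 65.1 ± 6.33, HSPE1 to 88.2 ± 3.18 and HSPA1A to 47.0 ± 0. Stress response genes fell in 6 of 10 with 4 not past (7 fell and 1 rose adjusted over the list alone), SESN2 to 13.5 ± 0.707, PSAT1 to 64.8 ± 3.18 and ASNS to 7.83 ± 0.589. The p53 targets fell in 6 of 9 with 3 not past (6 adjusted over the list alone), CDKN1A to 3.80 ± 0, TNFRSF10B to 5.00 ± 0 and AEN, a p53-induced nuclease, by 0.82 on the log2 scale. Camera gave adjusted p = 4.67e-07, 0.00873 and 0.00249, and adjusted p = 0.213, 0.339 and 0.290 with an estimated correlation. As with the other drugs, the DMSO libraries that stood apart lay on 1 side of every drug library in these genes. Heat shock calls were 7 without each library in turn, stress response calls 4, and p53 calls 1 without DMSO replicate 1, 3 without DMSO replicate 2 and 4 without levofloxacin replicate 2.

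Mitochondrially encoded genes fell in 7 of 13 with levofloxacin and 6 did not pass (8 fell and 1 rose adjusted over the list alone, and 8 of 13 fell with centring). MT-ND5 fell to 429 ± 8.49 and MT-CYB, of complex III, from 2646 ± 12.7 to 1551.5 ± 166. Replication-dependent histones, made in S phase, rose in 4 of 22 and 18 did not pass (4 rose adjusted over the list alone), with a median of 0.43. This list and the mitochondrial one were included as checks of RNA quality, so their calls need not be responses to the drug. HIST1H4B (ENSG00000278705, chromosome 6, 26026815 to 26027252) rose from 9.50 ± 0.707 to 27.0 ± 0, and HIST1H2AH and HIST1H2BD by 0.90 and 0.83, while the fourth, HIST1H2BG, holds a run of 30 adenines. Camera gave adjusted p = 0.0141 and 0.00873, and adjusted p = 0.720 and 0.517 with an estimated correlation. Mitochondrial calls were 0 without either DMSO library or levofloxacin replicate 2 and 1 without levofloxacin replicate 1. Histone calls were 2 without DMSO replicate 1 or levofloxacin replicate 1 and 1 without DMSO replicate 2.

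Immediate-early genes fell in 3 of 8 (JUND to 13.8 ± 0.354, SRF by 0.87 and IER5 by 0.75 on the log2 scale), with camera adjusted p = 0.199, while EGR1 stood at 15.5 ± 2.12 (−0.67, limma adjusted p = 0.108) and FOS at 21 ± 1.41 (0.67, adjusted p = 0.117). Cholesterol synthesis genes rose in 3 of 7 (IDI1 by 0.59, SQLE by 0.58, ACAT2 by 0.73). Lysosome genes fell in 2 of 7 (PSAP by 0.71, LAMP1 by 0.47) and autophagy genes in 0 of 5. The snoRNP proteins rose in 2 of 8 (NOP10 by 0.73, NHP2 by 0.44), host genes rose in 1 and fell in 4 of 11 (ZFAS1 by 0.79), box C/D snoRNAs fell in 4 of 88 and in the box H/ACA list 1 of 36 rose, SCARNA7, a box C/D RNA by its known class, and 1 fell (SCARNA4). Ribosomal protein genes rose in 5 and fell in 1 of 82 (RPL22L1 by 1.03, RPS26 by 0.54, RPL3 at −0.59). Camera adjusted p was 0.0773 or more for these lists. Hypoxia response genes rose in 3 of 4 (BNIP3 by 1.04, LDHA by 0.65, PGK1 by 0.56), and in 2 with centring. Of 2 tested YAP-TEAD targets GADD45A, a growth arrest gene, fell by 1.21 on the log2 scale, and neither passed with the other drugs, while with centring 1 was higher with dasatinib and 1 lower with hydroxychloroquine. The metal response genes FTH1 and FTL, ferritin subunits, did not pass with any drug, and with dasatinib 1 of 4 hypoxia genes fell (BNIP3L by 0.76, 0 with centring). TOP2A and TOP2B lay at 0.17 and 0.14 and did not pass. ERK output genes, dasatinib targets and the markers of fibroblasts, blood cells and squamous epithelium had 0 members among the tested genes. Leaving out DMSO replicate 2 ended every call of this paragraph except 1 immediate-early gene, 1 member of the H/ACA list, 2 C/D snoRNAs and 1 host gene, and DMSO replicate 1 all but 1 immediate-early gene, 1 snoRNP, 1 C/D, 1 host and 1 ribosomal protein gene. Levofloxacin replicate 1 left out kept 2 immediate-early, 1 host, 1 ribosomal protein and 1 YAP-TEAD call and gave 2 box C/D snoRNAs higher and 2 lower and 1 lysosome gene higher. Levofloxacin replicate 2 left out kept 2 immediate-early, 1 host, 1 ribosomal protein, 1 box H/ACA and 3 lower box C/D calls, with 1 box C/D snoRNA higher. Either left no cholesterol, snoRNP or hypoxia call.

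Limma called 1069 of 3630 genes with levofloxacin, 494 higher and 575 lower. Both counts of named genes that follow include genes with a run of at least 30 adenines, which are not read as expression. Of 59 named genes past the threshold 22 passed without each library in turn and all 59 kept their sign. The count was 186 without DMSO replicate 1, 230 without DMSO replicate 2, 413 without levofloxacin replicate 1 and 381 without levofloxacin replicate 2.

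**Figure D4:**
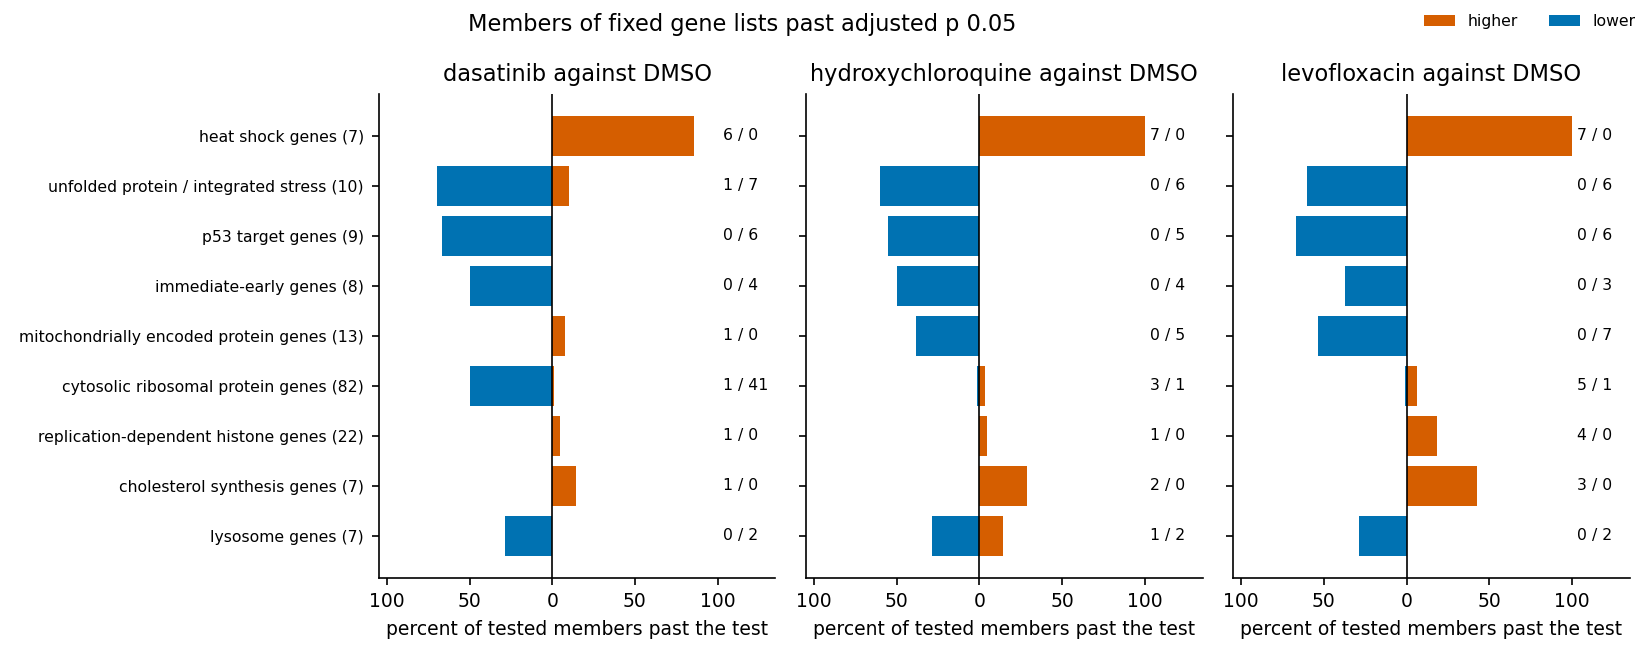
Percent of the tested members of 9 gene lists that were higher (right) or lower (left) at an adjusted p of 0.05 with each drug against DMSO, with the counts printed beside the bars. Heat shock genes were higher in 6, 7 and 7 of 7 members with dasatinib, hydroxychloroquine and levofloxacin, and 41 of 82 ribosomal protein genes were lower with dasatinib, 11 with centring.

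The overlap of responses asked how far the drugs moved the same genes. It covered only the 3630 genes with transcripts listed for all 3 drugs, and the simulations used the same genes. Listing differed between the drugs although their DMSO values were the same, and whether this raised the sharing was not tested. With all 3 drugs 138 genes were higher and 213 lower (181 and 186 with centring), and 4 genes were called in opposite directions (8 with centring). Of the genes higher with all 3 drugs 48 have a run of at least 30 adenines (46 with centring). Hydroxychloroquine and levofloxacin shared 363 higher and 300 lower genes, where 57.2 and 55.3 would be shared by independent lists. Unchanged groups against the same DMSO libraries shared at most 1 gene past the threshold, and lists of the same size ranked by limma's t shared 179 and 171 on average and at most 197 and 190. Dasatinib shared 149 and 241 with hydroxychloroquine (25.9 and 77.6 by independent lists) and 153 and 353 with levofloxacin (30.5 and 128). Lists of these sizes in unchanged groups shared 104 and 204 (at most 123 and 226), and 114 and 299.6 (at most 131 and 329). Log2 fold changes correlated across genes, which are not independent replicates, at 0.777 for dasatinib and hydroxychloroquine, 0.779 for dasatinib and levofloxacin and 0.893 for hydroxychloroquine and levofloxacin. Unchanged groups compared with the same DMSO libraries gave means of 0.494, 0.498 and 0.494 and at most 0.560, 0.574 and 0.567 in 100 simulations. Covariances were 0.265, 0.310 and 0.317 against simulated means of 0.0339, 0.0342 and 0.0338. With each drug of a pair set against a different DMSO library, so that no control was shared, the correlations were 0.678 and 0.722 for dasatinib and hydroxychloroquine, 0.720 and 0.707 for dasatinib and levofloxacin, and 0.845 and 0.784 for hydroxychloroquine and levofloxacin. The covariances were then 0.244 and 0.255, 0.296 and 0.292, and 0.309 and 0.294. This split was chosen after the other values were seen.

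Dasatinib minus hydroxychloroquine and dasatinib minus levofloxacin tested which genes differed between drugs directly. Mitochondrially encoded genes were higher with dasatinib in 11 and 10 of 13 members (13 and 12 adjusted over the list alone), MT-ND5 at 1104.5 ± 203 against 446 ± 26.9 and 429 ± 8.49 and MT-ND1 at 1372 ± 380 against 544 ± 1.41 and 649.5 ± 65.8. HSPA1B was higher with dasatinib than with hydroxychloroquine by 0.88 (0.60 to 1.17) and than with levofloxacin by 1.33 (1.05 to 1.61), and HSPA1A by 0.97 and 1.20. ZIC2 and ZNF503, zinc finger regulators of development, stood at 37.0 ± 8.49 and 90.5 ± 7.78 with dasatinib against 13.5 ± 0.707 and 34.0 ± 0 with levofloxacin. Ribosomal protein genes were lower with dasatinib in 32 and 44 of 82 (62 adjusted over the list alone in each), RPSA by 0.65 and 0.69 and RPL22 by 0.60 and 0.52 below hydroxychloroquine and levofloxacin, but with centring in 0 and 2. EGR1 was lower with dasatinib than with levofloxacin by 2.25 (95% interval of the difference −2.90 to −1.59) and FOS at −1.76, while JUND was higher by 0.95 than with hydroxychloroquine and by 0.66 than with levofloxacin, and IER5 by 1.04 than with levofloxacin. HIST1H2BD and 5 other histone genes of 22 were lower with dasatinib than with levofloxacin (6 adjusted over the list alone, 1 with centring), HIST1H2BD at −1.50. Camera gave the histone list adjusted p = 0.0709, and 0.0217 with centring. With an estimated correlation these were adjusted p = 0.694 and 0.716. Without dasatinib replicate 2 the mitochondrial counts were 3 and 2, the ribosomal ones 1 and 0 and the histone one 3. Without dasatinib replicate 1 the histone count was 3, and without either library of the other drug the mitochondrial and ribosomal counts were 0. The histone count was 0 without levofloxacin replicate 1 and 1 without levofloxacin replicate 2.

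For dasatinib minus hydroxychloroquine camera gave mitochondrial genes adjusted p = 3.61e-17 and ribosomal protein genes 1.44e-08, and adjusted p = 0.453 and 0.556 with an estimated correlation. It also gave immediate-early genes 6.30e-05, with 1 member higher and 1 lower (adjusted p = 0.453 with an estimated correlation), box C/D snoRNAs 3.52e-05, with 2 higher and 1 lower, a median of 0.04 and a mean of −0.02, and box H/ACA snoRNAs 1.74e-04 with 1 higher (both adjusted p = 0.520 with an estimated correlation, and 0.0565 and 0.0571 with centring). For dasatinib minus levofloxacin these values were 6.80e-12 for mitochondrial and 1.08e-09 for ribosomal protein genes, 0.0026 for box H/ACA snoRNAs with 2 higher and 0.00159 for box C/D snoRNAs with 1 higher and 1 lower, each with adjusted p = 0.694 with an estimated correlation, and centring gave the snoRNA lists 0.0762 and 0.0872. Heat shock genes were split, with 2 of 7, the neighbours HSPA1A and HSPA1B, higher with dasatinib than with hydroxychloroquine (median −0.33, mean 0.02, camera adjusted p = 0.701). Against levofloxacin the same 2 were higher and 2 lower, the latter HSPD1 by 0.51 and HSP90AA1 by 0.49, which centring ended (median −0.32, mean 0.06, camera adjusted p = 0.900). How reads that map to several places were counted is not given, so HSPA1A and HSPA1B may not be separate members. Immediate-early genes against levofloxacin had 2 higher and 2 lower, with a median of 0.15 and a mean of −0.22 (camera adjusted p = 0.303). Below hydroxychloroquine lay 1 hypoxia gene (PGK1 by 0.59) and 2 host genes (ZFAS1 by 0.51, SNHG8 by 0.59). Against levofloxacin 2 cholesterol synthesis genes (SC5D by 0.61, IDI1 by 0.44) and 1 host gene (SNHG8 by 0.80) were lower, and p53 targets had 1 higher (TNFRSF10B by 0.54) and 1 lower (TRIAP1 by 0.54). FOXF2, a forkhead factor among the YAP-TEAD targets, was higher by 0.83. Centring ended each of these lower calls. TOP2A and TOP2B did not pass in either contrast. Without either hydroxychloroquine library, or without levofloxacin replicate 1, every count in this paragraph was 0, and without levofloxacin replicate 2 only 1 heat shock gene passed.

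Limma called 536 genes between dasatinib and hydroxychloroquine, 74 higher and 462 lower, and 798 between dasatinib and levofloxacin, 163 higher and 635 lower. With centring 72 were higher and 15 lower, and 182 higher and 74 lower, of which 63 and 15, and 154 and 74, were called alike under both scalings. Both contrasts drew on the spread of the other groups, and limma called 0 genes in each without the DMSO libraries in the fit (1261 and 1299 at an unadjusted p under 0.05). It called 0 in the first contrast without hydroxychloroquine replicate 1 or replicate 2 (1078 and 941 unadjusted) and 174 without dasatinib replicate 2. In the second it called 0 without levofloxacin replicate 1 (1104 unadjusted), 6 without levofloxacin replicate 2 and 110 without dasatinib replicate 2. All 32 and 42 named genes past the threshold kept their sign in each of these fits.

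Hydroxychloroquine minus levofloxacin had 0 of 3630 genes past the threshold in limma, with 264 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0740. The genes with the smallest p-values are given as not passing. FOS stood at 4.50 ± 2.12 with hydroxychloroquine and 21 ± 1.41 with levofloxacin (−2.05, 95% interval −2.73 to −1.37, adjusted p = 0.262), and MIR222HG, a microRNA host, at 16.5 ± 3.54 and 37.0 ± 8.49. TSC22D3, a glucocorticoid-induced gene, stood at 18.3 ± 3.43 and 9 ± 0.404 (0.94, adjusted p = 0.262), and EIF5, a translation initiation factor, at 23.4 ± 0.530 and 14.4 ± 0.884. HSPA1B differed by 0.45 (0.16 to 0.73, adjusted p = 0.494). Camera passed histones (median −0.27, adjusted p = 3.16e-07) and immediate-early genes (median −0.32, adjusted p = 7.62e-05), with adjusted p = 0.423 for both with an estimated correlation and 0 members past in limma, and adjusted over the list alone 0 histones, and 1 immediate-early gene higher and 4 lower. The other lists had 0 members past, with camera adjusted p = 0.284 or more. With centring camera also passed ribosomal protein genes (adjusted p = 0.0488, and adjusted p = 0.986 with an estimated correlation), with 0 members past in limma. These intervals do not show that the drugs acted alike. Without levofloxacin replicate 2 limma called 3 genes.

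The diazirine comparison asked which transcripts a levofloxacin probe crosslinked to less when a competitor was present. The table shows the score in both groups without an input library. Limma called 0 of 2947 genes (153 at an unadjusted p under 0.05, smallest adjusted p 0.919). Replicates differed far more than in the RNA-seq, with an SD of the log2 ratio of 1.59 without and 1.93 with competitor in mid-length transcripts, and libraries correlated across genes at 0.733 and 0.667 within and 0.628 to 0.742 between groups. Genes with the smallest p-values were UBE2T, a ubiquitin-conjugating enzyme, at 61.0 ± 25.5 without and 1.5 ± 0.707 with competitor, and FTL at 231.5 ± 23.3 and 24.0 ± 18.4. TMEM14A, a membrane protein gene, stood at 22.0 ± 9.90 and 257.5 ± 117, and SLC39A9, a zinc transporter gene, was listed at 0 in both libraries without competitor and at 22.5 ± 7.78 with it. TOP2A stood at 124.5 ± 4.95 and 126.5 ± 74.2 and TOP2B differed by 0.41, neither past the threshold. None of the lists had a member past the threshold over all genes, and the 11 lists with at least 5 tested members had camera adjusted p = 0.932, and adjusted p = 0.938 with an estimated correlation. At this depth, 6.342e+05 to 2.824e+06 reads where resolved, and this spread, differences of 4-fold were not detectable in simulated data.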

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

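The test of whether the DMSO libraries lay apart was written after their place on the first component was seen, and median centring was added after the dasatinib median was seen. The fit takes genes from transcripts listed in all 3 RNA-seq tables, and genes whose transcripts were all outside them were tested in the 4 libraries of their own table. Of 656 such genes limma called 19 higher with dasatinib, of 212 it called 8 higher with hydroxychloroquine and of 520 it called 36 higher with levofloxacin, beside 19, 12 and 50 lower.

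The 3 drugs shared much of their change from DMSO, with HSPA1A and HSPE1 higher and SESN2 and PSAT1 lower with each. A filter on low DMSO values could produce such sharing. Yet among 752 genes with high DMSO values the lowest of the 3 correlations was 0.798, above the highest simulated there, 0.626. This argues against a filter on DMSO values alone. The tables list 11986, 10641 and 11591 transcripts for dasatinib, hydroxychloroquine and levofloxacin, although their DMSO values are the same. Their filter thus did not rest on DMSO alone, and a filter that also used drug values was not tested. A trend with transcript length could produce such sharing too, but with that trend removed the lowest was 0.783, above the highest simulated 0.574. DMSO libraries made or sequenced apart from the drug libraries may also give it, and the gap between DMSO and drug libraries was 63.2% of the range of the first component. The split was also seen in 57 transcripts with a run of at least 30 adenines, outside the named genes. Their median score was 24 and 28 in DMSO and 66 to 156 in the drug libraries. The genes of these transcripts are part of the first component too, so this is not a separate sign of a batch. Read steps were resolved in every drug library and in neither DMSO library. Such splits go with separate making or sequencing, but cannot tell it from an effect of the drugs. The question remains open, since the labels give no batch.

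The median gene lay lower with dasatinib than with DMSO, as did 41 of 82 ribosomal protein genes. A larger mitochondrial share of the library might cause this, yet with mitochondrially encoded transcripts left out of the scaling the median was −0.0957. This met the bound of −0.1 set for it, but without 1 library it ranged from −0.138 to −0.0503, so the question stays open. Counting noise in shallow libraries might cause it too, and in 224 long genes with high values the median was −0.0628, which met the same bound. Against levofloxacin the same genes lay at −0.196 with dasatinib, so this stays open as well.

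Genes with a run of at least 30 adenines, such as AC007098.1, ZNF302 and ADAM10, rose by like folds with every drug. If reads made of adenines alone were counted to every transcript with such a run, transcripts outside the named genes would rise as well, and 57 of them had a median log2 fold change of 2.28. What this possible explanation needs is present, and the reads themselves were not examined. The values are given without reading them as expression of those genes.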

How the results depend on the processing

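Median centring, the transcript with the highest mean, protein-coding genes only, all transcripts of 1 table, the fit without the DMSO libraries, the fit without genes with adenine runs and the split of the DMSO libraries were chosen after results were seen. Heat shock genes such as HSPA1A and HSPE1 and the lower SESN2 and PSAT1 kept their direction in every setting. The balance of higher and lower calls did turn with centring, from 420 and 349 to 340 and 461 with hydroxychloroquine, from 74 and 462 to 72 and 15 for dasatinib minus hydroxychloroquine and from 163 and 635 to 182 and 74 for dasatinib minus levofloxacin. In protein-coding genes 592 of 1046 levofloxacin calls were higher, against 494 of 1069. The counts of genes depended on the DMSO libraries and the contrasts between drugs on several further settings. Leaving out a replicate assumes that the lone library left varies like the other groups. Over such fits limma called 158 to 954 genes with dasatinib, 29 to 286 with hydroxychloroquine and 186 to 413 with levofloxacin. It called 0 to 522 for dasatinib minus hydroxychloroquine, 0 to 732 for dasatinib minus levofloxacin and 0 to 3 for hydroxychloroquine minus levofloxacin. The diazirine comparison stayed at 0. With only the 4 libraries of dasatinib and DMSO 628 genes passed, and 575 from all transcripts of that table. At least 1.5-fold were 687 with dasatinib, 483 with hydroxychloroquine and 698 with levofloxacin. Among calls between drugs these were 257 of 536 for dasatinib minus hydroxychloroquine and 311 of 798 for dasatinib minus levofloxacin. For dasatinib minus hydroxychloroquine and dasatinib minus levofloxacin, blocking on the replicate number gave 21 and 352, centring 87 and 256, the transcript with the highest mean 252 and 457, and no DMSO libraries in the fit 0 and 0. Restricted to protein-coding genes hydroxychloroquine minus levofloxacin had 1 call. With an estimated correlation camera passed 0, 0 and 0 lists for the 3 drugs, against 6, 5 and 5. Fry, which does not compare a list with the other genes, gave heat shock genes adjusted p = 2.16e-04, 2.15e-04 and 2.12e-04. It gave stress response genes 2.16e-04, 2.69e-04 and 2.12e-04 and p53 targets 8.64e-04, 6.33e-04 and 7.25e-04. Not all lists passed fry, with mitochondrially encoded genes at adjusted p = 0.155, 0.0553 and 0.0640. The replicate numbers of the RNA-seq libraries need not be pairs, as deviations of equal numbers correlated across genes at −0.044 to 0.097. In the diazirine libraries these deviations correlated at 0.035. Yet the mitochondrial share there was 31.8% and 32.1% in replicate 1 of the 2 groups and 21.4% and 22.0% in replicate 2. Pairing in that comparison is thus not settled. For dasatinib and hydroxychloroquine, dasatinib and levofloxacin, and hydroxychloroquine and levofloxacin, the correlations across genes were 0.814, 0.816 and 0.917 in genes above the median level and 0.715, 0.707 and 0.866 without genes with adenine runs. They were 0.776, 0.776 and 0.890 without DMSO replicate 1 and 0.795, 0.797 and 0.903 without DMSO replicate 2. With no shared DMSO library they were 0.678, 0.720 and 0.845 with the first drug against replicate 1 and 0.722, 0.707 and 0.784 with it against replicate 2. The cause of these differences was not tested. Count methods such as edgeR, DESeq2 and other normalisations of counts, and alternatives on thresholds of the authors, were not run. The reason was that the score was taken to be rounded RPKM, not counts. Rounding and the depth of the libraries limit what short and low transcripts can show, such as snoRNAs and EGR1 at 2.5.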

Other observations

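The lists in this part were chosen after the results were seen. Their camera p-values were adjusted over these chosen lists alone, so they describe the lists and do not test them. Amino acid transporters, which bring substrates for protein synthesis into the cell, fell in 6 of 6 tested members with each drug. SLC7A11, the cystine transporter, fell by 2.63, 2.14 and 2.14 on the log2 scale with dasatinib, hydroxychloroquine and levofloxacin, and SLC7A5, of large neutral amino acids, by 1.47, 1.73 and 2.06. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, fell in 8, 4 and 4 of 10 and rose in 0, 1 and 1, with SARS falling by 1.23, 1.05 and 1.06. Camera gave the transporters adjusted p = 1.96e-04, 5.48e-07 and 7.92e-06, and adjusted p = 0.128, 0.0524 and 0.0724 with an estimated correlation. For the synthetases it gave 0.00166, 0.0265 and 0.0416, and adjusted p = 0.128, 0.102 and 0.138 with an estimated correlation. Without DMSO replicate 1 the transporters that fell with hydroxychloroquine numbered 3 and the synthetases 4, 0 and 3 for the 3 drugs, and without DMSO replicate 2 they numbered 3 and 5, 1 and 3. Hydroxychloroquine replicate 1 left out gave 2 synthetases, and the 1 synthetase that rose did not pass without any 1 library.

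Proteasome subunits, which degrade proteins, rose in 4, 11 and 15 of 24 with dasatinib, hydroxychloroquine and levofloxacin, PSMA4 by 0.37, 0.84 and 0.91. Subunits of TRiC, the chaperonin that folds actin and tubulin, rose in 1, 6 and 6 of 8, CCT6A by 0.52, 0.77 and 0.88, while CCT4 lay at 0.28 with dasatinib (limma adjusted p = 0.068). Camera gave proteasome genes adjusted p = 0.00166, 3.14e-07 and 4.78e-06 and TRiC genes 0.00971, 1.03e-04 and 1.31e-04. With an estimated correlation these were adjusted p = 0.140, 0.0524 and 0.0724, and adjusted p = 0.128, 0.0524 and 0.0724. With centring and an estimated correlation camera gave both lists adjusted p = 0.0602, 0.0392 and 0.0413. The values under 0.05 for hydroxychloroquine and levofloxacin are no support, since both lists were chosen after these data were seen. With centring 7 proteasome and 2 TRiC genes rose with dasatinib. Proteasome calls were 0, 1 and 5 without DMSO replicate 1 and 0, 0 and 3 without DMSO replicate 2, and TRiC calls 0, 0 and 3 without either. Without replicate 1 of each drug they were 1, 3 and 6 for the proteasome and 1, 3 and 6 for TRiC, and without replicate 2 they were 4, 4 and 4, and 1, 2 and 3, with 1 proteasome gene lower for dasatinib.

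Transfer RNAs of the mitochondrial genome rose in 4 and fell in 4 of 22 with dasatinib, rose in 1 and fell in 6 with hydroxychloroquine and fell in 8 with levofloxacin. Camera gave adjusted p = 0.0229, 0.320 and 0.0106, and adjusted p = 0.431, 0.683 and 0.360 with an estimated correlation. With centring the dasatinib call ended (adjusted p = 0.0983, 4 higher and 2 lower), and the other counts stayed. Between dasatinib and hydroxychloroquine 1 was higher with dasatinib, and 0 with centring. Camera gave adjusted p = 1.00e-06, and adjusted p = 0.210 with an estimated correlation. Hydroxychloroquine minus levofloxacin had 0 past in limma, with camera adjusted p = 1.01e-04, and adjusted p = 0.533 with an estimated correlation. Without DMSO replicate 1 the counts were 3 higher, 0 and 2 lower for the 3 drugs. Without DMSO replicate 2 they were 2 higher and 2 lower, 0, and 1 higher and 5 lower. Without replicate 1 of each drug they were 3 higher and 2 lower, 5 lower and 5 lower, and without replicate 2 they were 2 higher and 1 lower, 1 higher and 1 lower, and 6 lower. Between dasatinib and levofloxacin 8 were higher with dasatinib (camera adjusted p = 6.13e-11, and adjusted p = 0.159 with an estimated correlation), 6 with centring, 4 without dasatinib replicate 1 and 0 without dasatinib replicate 2 or either levofloxacin library. Copies of U6, the spliceosomal RNA, fell in 6, 2 and 1 of 31 (2, 2 and 2 with centring), and the uncentred counts were 1, 0 and 0 without either DMSO library, 5, 1 and 0 without replicate 1 and 11, 1 and 1 without replicate 2 of each drug, with 1 higher for dasatinib. In the diazirine comparison 24 tested U6 copies had a median of 1.58 and a mean of 0.60 without competitor against with it, with camera adjusted p = 0.108, adjusted p = 0.918 with an estimated correlation and 0 members past the threshold in limma.

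The deposited tables carry p-values of the authors. At an unadjusted p under 0.05 these held 4381 of 11986 transcripts with dasatinib, 928 higher and 3453 lower. With hydroxychloroquine they held 4169 of 10641, 2238 higher and 1931 lower. The p-values of these drugs each test a single direction, so counting both directions at 0.05 is a looser rule. For the diazirine probe, whose p-values cover both directions, 323 of 7547 transcripts lay under 0.05. That share is below the 0.05 that chance alone would give. The largest deposited p was 0.5 in the dasatinib and hydroxychloroquine tables, and the levofloxacin table has no such column.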
